A study of Saccharomyces cerevisiae with 4 samples.

How the data were processed

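RNA of budding yeast (Saccharomyces cerevisiae) was labelled and hybridised to 4 one-colour Affymetrix arrays, per the labels. The arrays hold 1 culture of an ada1 deletion strain, 1 culture of a gcn5 deletion strain and 2 samples of the wild-type strain BY4742, a laboratory haploid of mating type alpha from which the deletions were made. Nothing in the labels says whether the wild-type samples came from separate cultures, so p-values measure only the spread between these samples, which may be technical. The labels give 200 ng of total RNA per labelling with biotin.

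The deposited values are MAS5 intensity per probe set on a linear scale, per the submitters' processing notes. The version of MAS5, its scaling target and its detection calls are not given in the sources used here. MAS5 summarises the perfect-match and mismatch probes of a probe set and scales each array. The arrays still differed in overall level, with medians of 413 to 525 and means of 1212 to 1426. They also differed in the shape of their distributions. The table held 5716 probe sets. Of these, 5498 had 1 gene symbol in the platform annotation, 0 had several and 218 had none. All probe sets with a symbol were matched to the RefSeq gene table of assembly R64 through the gene identifier, which updated 12 symbols, and that table was used only for names and for which genes neighbour each other. Probe sets ending in _s_at or _x_at can detect several similar transcripts, and values from them are marked in the text. Of the 5449 genes, 47 had several probe sets, and the probe set with the highest mean log2 signal stood for the gene.

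The table held no probe sets marked as controls or as of another organism, and the background level was therefore taken as the 20th percentile of the mean log2 signal, a signal of 166. Of 5667 genes and unnamed probe sets, 4541 reached this level on average and were tested, 4393 of them named and 148 unnamed. HFI1 and GCN5 lay below it on average because of their own deletions, and their signals are given without a test. Where every array of a group lay below the background level, the change is given as at least N-fold, which sets the brighter group's mean against the background level. The number of arrays limits the precision.

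Differences were tested on log2 signal with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with a trend of the spread on the mean). All 4 arrays entered a single fit of 3 groups. The only residual degree of freedom (1) came from the wild-type pair, so each lone deletion array was assumed to vary as the wild-type arrays do. P-values were adjusted over all genes tested by the Benjamini-Hochberg method, and a gene is called changed at an adjusted p under 0.05. The prior degrees of freedom were infinite on the values as deposited, so that every gene took the spread of the trend at its mean signal and genes with an unusual spread got p-values that are too small. After quantile normalization the prior degrees of freedom were 9.17, and adjusted p-values from that fit are given beside the main ones for the leading genes. Counts of genes that were called and also differed by 2-fold or more against each array of the other group are given beside the counts of calls. The statement about both strains used simulated unchanged arrays (100 draws) that share the wild-type arrays.

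Simulated data tested the fit for the comparison of ada1 deletion with wild type, with 200 of 4541 genes changed. With the spread of the trend, 46.6 percent of genes with a log2 change of 1 and 94.7 percent with a log2 change of 2 were recovered, and 5.23 percent of calls were false. A second simulation took the trend of the quantile-normalized fit instead and varied the spread between genes around it. Its values were 84.9 and 99.9 percent, with 7.65 percent of calls false. The wild-type arrays differ less after quantile normalization (median absolute log2 difference 0.152, against 0.256 as deposited). The higher recovery therefore does not show an effect of the variation between genes.

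The arrays of the ada1 deletion strain and of wild-type replicate 1 reached signals of 21989 and 23746. Those of the gcn5 deletion strain and of wild-type replicate 2 reached only 12244 and 11804. The labels name no batch, and these pairs were treated as a technical batch, with each deletion array also compared with the wild-type array of its own range. A fit with the pair as a block left 0 residual degrees of freedom and gave values without a test.

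Before the data were examined, 38 gene lists, the alternatives and the rule for named genes were fixed. The text names the deleted genes, the 10 largest rises and the 10 largest falls among genes that were called and differed by 2-fold or more against each array of the other group, ranked by the fitted log2 difference, up to 4 members of each list described with the largest differences, and the 10 genes with the largest mean difference among those called in both strains in the same direction. A rank that rests on a signal under the background level is not firm, and the bound given for such a gene can lie under 2-fold, as for FMP46 between the deletion strains. Other genes are named from the lists or where a small count is spelled out, and were then chosen after their values were seen. A list with 3 or more tested genes was described by its median log2 difference and by the percentile of that median among 10000 random lists of equal size, matched in 10 bins of mean signal. A list was said to stand apart at a percentile of at most 0.5 or at least 99.5 with the same sign against each wild-type array, a condition that has no counterpart between the wild-type arrays or between the deletion arrays. 4 lists had fewer tested genes. The alternatives were quantile normalization, scaling to a common median, log2 of the signal plus 32, no filter and a stricter filter on dim probe sets, a single variance prior, the 2-fold rule, fits of fewer or merged groups, each wild-type array left out, and averaged probe sets. Comparisons within array pairs, signals raised to the background level, and quantile normalization combined with the 2-fold rule, were added after the data were seen. No genome was used here, and the planned comparison of promoters with a TATA box was not analysed here. Figures were drawn with matplotlib 3.10.9.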

Results

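Messenger RNA levels were measured across the yeast genome in wild-type cells and in strains that lack a subunit of SAGA, a coactivator complex that modifies histones at promoters. HFI1, also called ADA1, encodes a structural subunit of SAGA, and GCN5 encodes its histone acetyltransferase. Cells grew in rich glucose medium (YPD) to exponential phase. The ada1 deletion strain and the gcn5 deletion strain were measured on 1 array each and wild type on 2 arrays. The median signal was 457 for the ada1 deletion strain, 525 for the gcn5 deletion strain, and 413 and 494 for wild-type replicates 1 and 2.

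The deleted genes were read first. HFI1 gave a signal of 6.70 in the ada1 deletion strain, against 246 and 279.8 in wild type and 372 in the gcn5 deletion strain. GCN5 gave 3.28 in the gcn5 deletion strain, against 309 and 385 in wild type and 333 in the ada1 deletion strain. LEU2, LYS2 and URA3, which BY4742 lacks, gave signals of at most 38.9 on every array. HIS3, whose allele in this strain lacks only an internal part, gave 1517 to 1798 and checks nothing if its probes lie outside that part. The 18 tested genes of other SAGA subunits and the 28 of TFIID and Mediator had no calls in either strain (limma), also when adjusted over the list alone. At an unadjusted p under 0.05 the counts were 1 and 0 in the ada1 and 2 and 0 in the gcn5 deletion strain. Their medians were 0.23 and 0.15 in the ada1 deletion strain and 0.33 and 0.29 in the gcn5 deletion strain. The median over all tested genes lay 0.08 above wild type on the log2 scale in the ada1 deletion strain and 0.15 above it in the gcn5 deletion strain, and list percentiles are relative to genes of like signal. Of the 34 lists measured, 17 passed the percentile limits in the ada1 and 7 in the gcn5 deletion strain (15 and 6 with the same sign against each wild-type array), and 8 passed them between the wild-type arrays themselves. Those 8, with medians of replicate 1 relative to replicate 2, were glycolysis and fermentation (0.84), ribosomal proteins (0.73), alpha-specific genes (0.32), amino acid synthesis controlled by Gcn4 (0.20), the iron regulon (0.05), general stress genes (0.01), the proteasome (-0.21) and ribosome biogenesis (-0.32).

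The comparison of the ada1 deletion strain with wild type asked which transcripts depend on this structural subunit. Genes of the PHO regulon and alpha-specific genes were among those that fell furthest. PHO84, the high-affinity phosphate transporter, gave a signal of 18.4 against 12610.3 and 7020.3 in wild type, at least 56.8-fold lower. SPL2, which acts in phosphate homeostasis, was at least 20.3-fold lower, and the alpha-factor gene MF(ALPHA)2 at least 56.6-fold lower. SER3, which encodes an enzyme of serine synthesis, rose most, from 342 and 321 to 5332 (log2 difference 4.01 ± 0.29 SE, adjusted p = 1.09e-40, limma; 7.61e-07 after quantile normalization).

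The test called 383 of 4541 genes, 124 higher and 259 lower. Of these, 210 also differed by 2-fold or more against each wild-type array, 35 higher and 175 lower. After quantile normalization, 298 genes were called higher and 394 lower, and after scaling to a common median 363 and 377. By rank of the fitted difference, the other leading falls were of CWP1, a cell wall mannoprotein (at least 23.1-fold), PHO3, an acid phosphatase repressed by thiamine (at least 13.3-fold), the sodium-phosphate cotransporter PHO89 (at least 9.25-fold), PHM6 (at least 5.18-fold), the secreted glycoprotein YGP1 (at least 10.3-fold) and the stress protein DDR48 (at least 15.3-fold). PHO11, read by a probe set that can also detect its near-copy PHO12, fell by 5.14 ± 0.23 SE on the log2 scale. Adjusted p-values of these 10 leading falls were at most 1.63e-29 as deposited and at most 1.95e-06 after quantile normalization. THI13, read by a probe set shared with other THI genes of thiamine synthesis, was at least 5.77-fold higher than wild type. The sulfate permease gene SUL2 was at least 3.13-fold and HBN1, a putative nitroreductase gene, at least 3.56-fold higher. YIL014C-A rose by 2.39, MET3 (ATP sulfurylase) by 1.81, HUG1 (a gene of the DNA damage response) by 1.75, the lipid droplet gene PLN1 by 1.74, the peroxisome gene PEX27 by 1.62 and SPG5 by 1.59 on the log2 scale. The largest adjusted p among the 10 leading rises was 0.000983 as deposited and 0.000757 after quantile normalization.

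Of the 14 tested genes of the PHO regulon, which responds to phosphate starvation, 11 fell and none rose, with 13 falling when adjusted over the list alone. The list median was -2.36 (percentile 0), or -2.07 with dim genes set at the background level. All 4 alpha-specific genes fell, with a median of -3.17. Among them the a-factor receptor gene STE3 went from 3645 and 3971 to 423 and the alpha-agglutinin gene SAG1 from 6340.2 and 5328 to 644. Of 23 pheromone response and haploid-specific genes, 6 fell (8 adjusted over the list alone) and the median was -0.44. These included FAR1, which arrests the cell cycle in response to pheromone, with 154 against 683 and 882, and RME1, with 204 against 934 and 1058.

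Of 15 daughter-specific and cell separation genes, 12 fell (14 adjusted over the list alone), with a median of -1.39 and percentile 0. The bud-site gene BUD9 had a signal of 54.3 against 361 and 421, and the chitinase gene CTS1 1782 against 8932 and 5729.6. DSE3 had 255 against 844 and 1128, and AMN1 713 against 2496 and 2898. Of 26 genes expressed at G2-M and M-G1, 8 fell (8 adjusted over the list alone), among them the mitotic cyclin gene CLB1 (104 against 629 and 791), and the median was -0.45, or -0.40 with dim genes at the background level.

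Of 31 general stress genes, 11 fell and none rose (12 and 1 adjusted over the list alone), with a median of -0.52, which was -0.37 with dim genes at the background level and -0.12 without the filter on dim probe sets. The glycerol synthesis gene GPD1 fell from 2781 and 2259.9 to 282, and DDR2 gave 30.9 against 518 and 377. Hexose transport genes had 4 falls of 8 tested (4 adjusted over the list alone) and a median of -1.04. HXT1, a low-affinity glucose transporter, fell from 2569.8 and 2610.4 to 278, and HXT7, nearly identical to HXT6, gave 138 against 621 and 1031. Nitrogen catabolite repressed genes had 6 falls of 15 (7 adjusted over the list alone, median -0.57, but -0.04 without the filter, at percentile 9.25 and no longer apart), led by the amino acid permease genes TAT1 and DIP5 at 353 and 514 against wild-type signals of 2161 to 2797. Drug resistance genes had 4 falls of 12 (6 adjusted over the list alone, median -0.59), among them the transporter genes QDR2 (38.6 against 509 and 599) and TPO4 (46.9 against 296 and 307). The iron regulon (4 falls and 1 rise of 21, and the same numbers adjusted over the list alone) and ribosome biogenesis genes (5 falls of 88, 5 adjusted over the list alone) also stood apart, with medians of -0.26 and -0.17. The ribosome biogenesis median was -0.32 against wild-type replicate 2 and -0.00406 against replicate 1.

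Higher lists stood apart as well. Of 22 sulfur and methionine genes, 8 rose and none fell, also when adjusted over the list alone, with a median of 0.61 and percentile 100. MET10 went from 803 and 979 to 2492, and MET13 from 173 and 143 to 463. Heat shock factor chaperones had 3 rises of 21 (4 adjusted over the list alone, median 0.49), SSE2, HSP82 and CPR6, with SSE2 going from 272 and 217 to 669.7. Respiratory chain genes had 4 rises and 2 falls of 32, the same numbers adjusted over the list alone, and a median of 0.29. The falls were of COX5B (127 against 561 and 747), an isoform of cytochrome c oxidase subunit Va, and CYC1 (213 against 489 and 641), the main cytochrome c gene. The 6 tested COS genes near telomeres, of which COS2, COS4 and COS7 have probe sets that can detect similar genes, had a median of 0.51 without a call (limma), also when adjusted over the list alone, and 1 had an unadjusted p under 0.05, while 2 were called higher after quantile normalization. Without the filter the COS median was 0.44 at percentile 97.7, no longer apart. Calls were lost after scaling to a common median for HXT3 (adjusted p = 0.138, from 0.000125 to 0.138 over the alternatives), CPR6 (0.116, from 0.00213 to 0.151, and 4 alternatives in all) and MF(ALPHA)1 (0.0613, from 6.22e-06 to 0.0613) and with a single variance prior for HSP82 (0.120, from 4.33e-05 to 0.120), and without the filter on dim probe sets the hexose transport median turned to 0.25 at percentile 77.5, no longer apart. With signals under the background level raised to it, TPO4 (-0.86 ± 0.26 SE on the log2 scale, from -2.69 ± 0.36) and BUD9 (-1.23 ± 0.31, from -2.84 ± 0.38) lost their calls. So did HXT3 (-1.38 ± 0.37), CPR6 (0.89 ± 0.23) and CYC1 (-1.39 ± 0.39), at unchanged differences and only through the refitted spread and its 8.44 prior degrees of freedom. A difference between the array pairs in signal range entered these averages, and against replicate 1, of its own range, the ada1 deletion array differed by 2-fold or more in 120 genes upwards and 200 downwards, against 69 and 229 with replicate 2.

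The comparison of the gcn5 deletion strain with wild type asked the same of the acetyltransferase. Alpha-specific genes and genes of the PHO regulon fell, and ARG3, ARG1, SNZ1 and HSP12 were among those that rose most. MF(ALPHA)2 fell from 10769.5 and 8181 to 204 (log2 difference -5.52 ± 0.22 SE, adjusted p = 3.80e-124, limma; 5.48e-08 after quantile normalization). PHO11 fell by 5.05 ± 0.23 SE on the log2 scale by a probe set that can also detect PHO12. ARG3, which encodes ornithine carbamoyltransferase, rose from 171 and 84.6 to 2310.1 (log2 difference 4.26 ± 0.37 SE, adjusted p = 1.74e-27; 0.000137 after quantile normalization), or 3.78 ± 0.31 with the replicate 2 signal, which lies under the background level, raised to it.

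The test called 211 genes, 96 higher and 115 lower, and 99 of them also differed by 2-fold or more against each wild-type array, 30 higher and 69 lower. After quantile normalization 143 genes were called higher and 247 lower, and after scaling to a common median 214 and 276, while with signals under the background level raised to it 51 and 55 were called. The other leading falls were of SPL2 (at least 20.3-fold), SAG1 (by 4.10 on the log2 scale), PHO3 (at least 13.3-fold), FAR1 (at least 4.68-fold), PHM6 (at least 5.18-fold), YGP1 (at least 10.3-fold), the acid phosphatase gene PHO5 (by 3.52) and the cell fusion gene FUS1 (at least 2.62-fold). Adjusted p-values of the 10 leading falls were at most 4.49e-17 as deposited and at most 3.71e-06 after quantile normalization. The other leading rises, on the log2 scale, were of ARG1, argininosuccinate synthetase (2.04; 1.35 without wild-type replicate 2 and 2.73 without replicate 1, from signals of 5360.0 against 2099 and 805), SNZ1, a vitamin B6 gene (2.04), the small stress proteins HSP12 (2.03) and HSP26 (1.49), the cell wall mannoprotein gene TIR3 (1.94), PRY1 (1.73), HPF1 (1.61), YDL085C-A (1.60) and FIT2, a mannoprotein of iron uptake (1.49). The largest adjusted p among the 10 leading rises was 0.00331 as deposited and 0.0127 after quantile normalization, for ARG1.

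In the PHO regulon 12 of 14 tested genes fell and none rose (13 falls adjusted over the list alone), with a median of -1.47. PHO84 fell from 12610.3 and 7020.3 to 3299 and the polyphosphate synthesis gene VTC3 from 4964 and 4955 to 973. Of the 4 alpha-specific genes, 3 fell (4 adjusted over the list alone, median -3.49), and the remaining gene, MF(ALPHA)1, gave 4967 against 11518 and 8012. Pheromone response and haploid-specific genes had 8 falls of 23 (10 adjusted over the list alone, median -0.54), among them AGA1, the anchor of a-agglutinin (254 against 1139.6 and 1195), and SST2, a regulator of pheromone signalling (166 against 655 and 672). Nitrogen catabolite repressed genes had 2 falls of 15, TAT1 and CAR2 (3 adjusted over the list alone), and a median of -0.22 (percentile 0.15; 0.57 after quantile normalization and 1.29 without the filter, where the median turned to 0.01, and apart in neither).

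General stress genes had 5 rises and 1 fall of 31 (12 and 2 adjusted over the list alone), with a median of 0.45 and percentile 99.8, or medians of 0.24 after quantile normalization and, at an unchanged percentile, 0.28 after scaling to a common median, which shifts all genes alike. The rises were of HSP12, HSP26, GLC3, TSL1 and ALD4, and the fall was of YGP1. TSL1, a subunit of trehalose synthase, went from 683 and 674 to 1569.6, and the glycogen branching gene GLC3 from 216 and 213 to 503. Respiratory chain genes had 1 rise, CYT1, and 1 fall, COX9, of 32, the same adjusted over the list alone, and a median of 0.24 (percentile 99.7), which was 0.07 at the same percentile after scaling to a common median. Of 46 tested genes of amino acid synthesis controlled by Gcn4, 6 rose and 2 fell (8 and 4 adjusted over the list alone). The rises were of ARG1, ARG3, ARG4, ARG8, ARO3 and HIS5 and the falls of LYS9 and LYS20, and the list did not stand apart (median 0.04, percentile 96.0), except after quantile normalization (0.17, percentile 99.9), while the shift of all genes by scaling to a common median put the median at -0.13 with the percentile unchanged. FIT2 lost its call after scaling to a common median (adjusted p = 0.136, from 6.49e-05 to 0.136 over the alternatives), and COX9 lost its call without the filter on dim probe sets and with a single variance prior (0.0969 and 0.301, from 0.00112 to 0.301), the latter also ending the calls of TAT1 (0.0709, from 1.55e-07 to 0.0709) and CAR2 (0.216, from 1.96e-05 to 0.216). With signals raised to the background level YDL085C-A, FIT2, HSP26, GLC3, CYT1, COX9 and CAR2, none with a signal under it, kept their log2 differences (1.60, 1.49, 1.49, 1.23, 1.16, -0.81 and -0.89, with SE of 0.23 to 0.40 before and 0.19 to 0.42 after). Their calls ended only through the refitted spread and its 8.44 prior degrees of freedom. Without replicate 2, the wild-type array of its own signal range, the gcn5 deletion array differed from wild type by 2-fold or more in 346 genes, 240 higher and 106 lower, against 139 without replicate 1, 49 higher and 90 lower, and 113 with both, 41 higher and 72 lower.

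**Figure D1:**
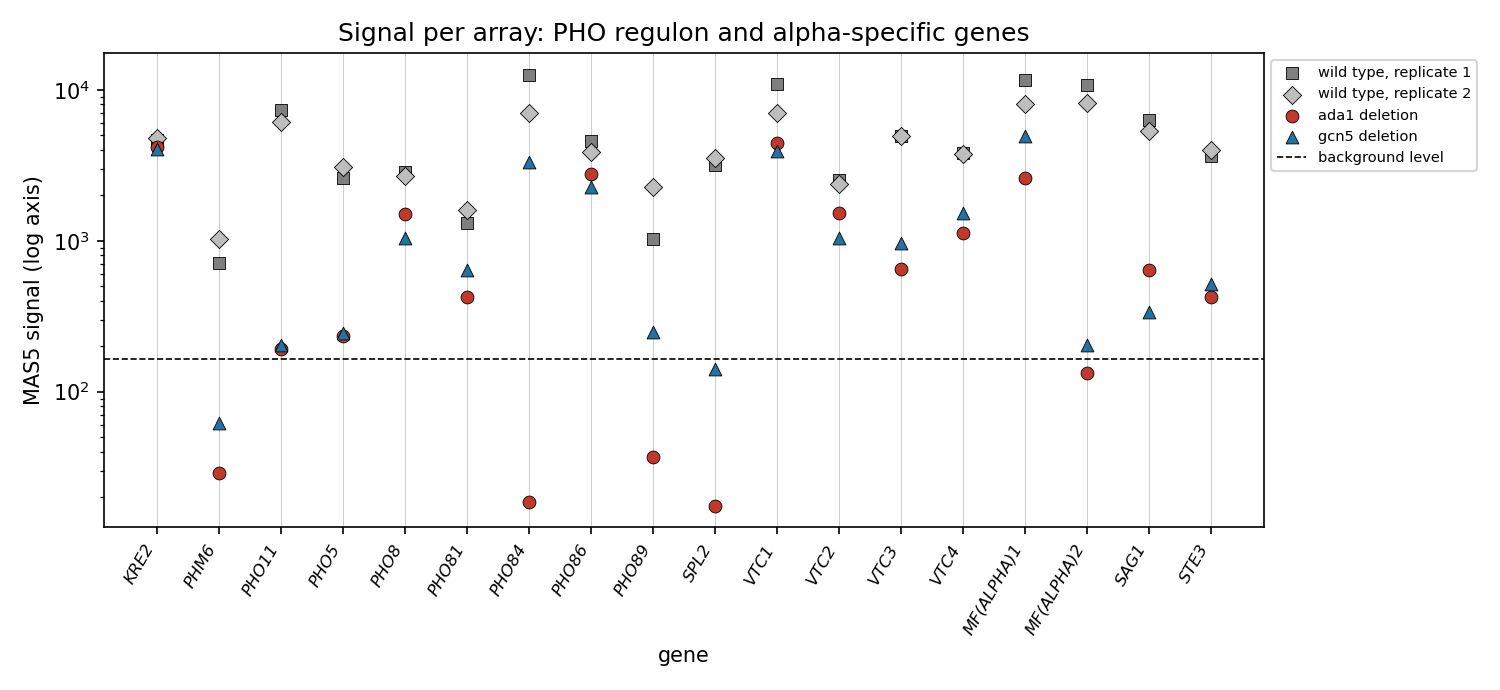
MAS5 signal on a log axis for the 14 tested PHO regulon genes and the 4 alpha-specific genes, with 1 point per array and the background level as a dashed line. PHO84 lies at 18.4 in the ada1 deletion strain and 3299 in the gcn5 deletion strain, while PHO11 lies at 191 and 203.

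**Figure D2:**
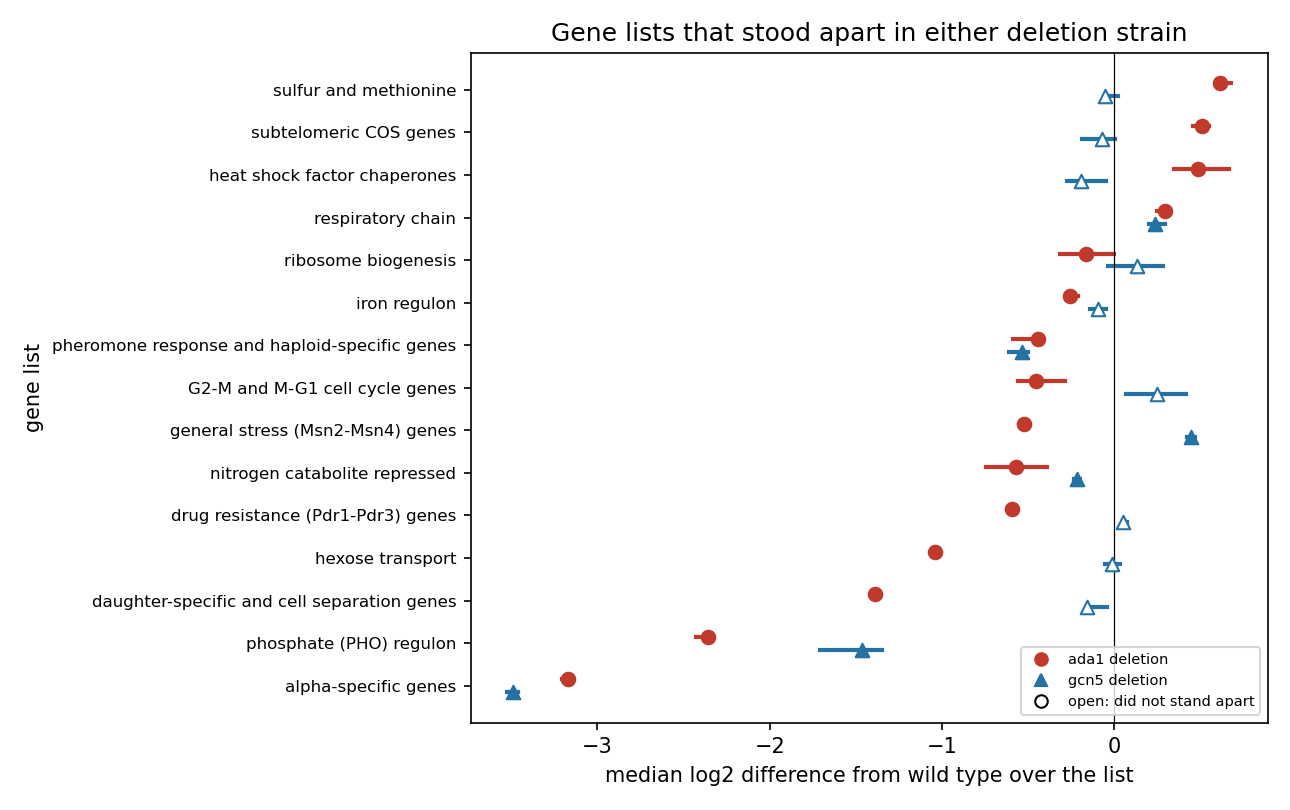
Median log2 difference from wild type (horizontal axis) for each gene list that stood apart in either deletion strain, such as general stress at -0.52 in the ada1 and 0.45 in the gcn5 deletion strain. Circles show the ada1 and triangles the gcn5 deletion strain, open symbols mark lists that did not stand apart in that strain, and each line joins the medians against the single wild-type arrays.

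Genes called in both strains were set side by side to ask which changes the strains share. Genes of the PHO regulon and alpha-specific genes fell in both. The 10 genes with the largest mean difference were SPL2, MF(ALPHA)2, PHO84, PHO11, PHO3, PHM6, YGP1, PHO89, SAG1 and PHO5, and all fell. PHO5 had 233 in the ada1 and 246 in the gcn5 deletion strain against 2595 and 3075 in wild type, and PHO89 had 36.8 and 250.0 against 1028 and 2285.

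In all, 84 genes were called in the same direction, 18 higher and 66 lower, and 21 in opposite directions, while with signals raised to the background level 5 were called higher and 37 lower in both. Independent lists of these sizes would share 2.62 higher and 6.56 lower genes, and simulated unchanged arrays against the same wild-type arrays shared 0.02 on average and at most 1. Unchanged arrays give almost no calls, so this does not measure what the shared wild-type arrays add, and part of the excess of shared calls over independent lists may come from the shared wild-type arrays. Among the shared genes 22 of 84 differed between the strains by the test of ada1 against gcn5 deletion, as did 131 of the 278 genes called in the ada1 deletion strain alone and 44 of the 106 called in the gcn5 deletion strain alone. Across genes, which are not independent replicates, the log2 differences correlated with r = 0.408 (simulated 0.336) and a covariance of 0.132 (simulated 0.0475, a difference of 0.0845). With each deletion array against a wild-type array of its own, the covariance was 0.139 within the pairs of like signal range. Across those pairs the covariance was 0.0533. The simulation drew arrays without any difference between pairs, so its values do not show what unchanged arrays of this design would give.

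**Figure D3:**
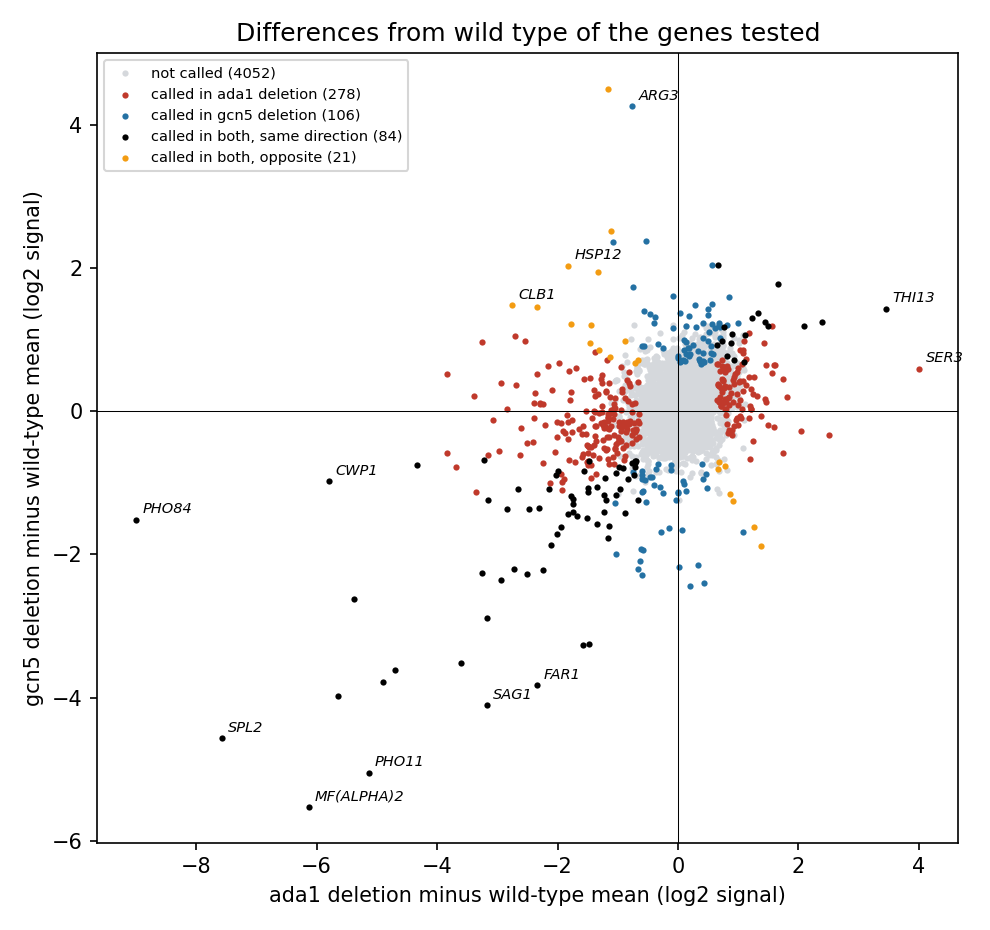
Log2 difference from the wild-type mean in the ada1 deletion strain (horizontal axis) against that in the gcn5 deletion strain (vertical axis), with 1 point per tested gene, coloured by call. Of the 84 genes called in the same direction 66 lie at the lower left, and the 21 called in opposite directions lie at the upper left and lower right.

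The deletion strains were compared with each other to ask where loss of the structural subunit and of the acetyltransferase differ. PHO84 had the largest fitted difference, with 18.4 in the ada1 and 3299 in the gcn5 deletion strain, at least 19.9-fold lower in the former (adjusted p = 4.00e-175, limma; 1.42e-08 after quantile normalization). ARG3 was at least 13.9-fold and CWP1 at least 11.8-fold lower in the ada1 deletion strain. SER3 was higher there by 3.41 ± 0.33 SE on the log2 scale, with 5332 against 501.

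The test called 284 genes, 91 higher and 193 lower in the ada1 deletion strain, of which 239 differed by 2-fold or more. After quantile normalization 289 were called higher and 288 lower, and after scaling to a common median 289 and 268, while with signals raised to the background level 40 and 95 were called. By rank of the fitted difference, the others downwards were of QDR2 (at least 4.77-fold), CLB1 (at least 11.9-fold), RPI1 (at least 3.87-fold), HSP12 (at least 11-fold), the cyclin gene PCL5 (-3.79 on the log2 scale), YGR035C (at least 6.90-fold) and AAD4 (at least 4.84-fold). Those upwards were of GRX8 (at least 5.20-fold), YEA4 (at least 3.07-fold), FMP46 (at least 1.96-fold), HUG1 (at least 3.53-fold), SUL2 (at least 3.13-fold), IMD2, read by a probe set that can detect similar genes (at least 4.32-fold), the cell wall gene TIP1 (2.77), the peptide transporter gene PTR2 (2.20) and PAU23 (3.26). Against the wild-type array of its own signal range, PAU23 turned to -0.65 and AAD4, with ada1 and replicate 1 signals under the background level, lay at -0.28 once these were raised to that level. Neither was called after quantile normalization (adjusted p = 0.0971 and 0.105, from 3.19e-42 to 0.273 and from 8.46e-34 to 0.176 over the alternatives) or with signals raised to the background level, where PAU23 kept its difference with an SE of 1.33 instead of 0.37 and AAD4 lay at -2.27 ± 0.76. Raised signals also ended the calls of YEA4 (1.62 ± 0.38, from 2.83 ± 0.45), IMD2 (2.11 ± 0.55, from 2.64 ± 0.45) and FMP46 (0.97 ± 0.24, from 2.49 ± 0.40).

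The daughter-specific list had the median furthest from 0 among all lists measured, with 12 of 15 genes lower in the ada1 deletion strain (13 adjusted over the list alone) and a median of -1.47 (-1.39 with dim genes at the background level). General stress genes had 12 of 31 lower (17 adjusted over the list alone) and a median of -0.999 (only -0.64 with dim genes at the background level), and G2-M and M-G1 genes 6 of 26 (9 adjusted over the list alone) and -0.82 (-0.77 at that level). Sulfur and methionine genes had 5 of 22 higher, also when adjusted over the list alone, with a median of 0.71 (0.58 at that level). In the PHO regulon PHO84, SPL2 and PHO89 were called lower in the ada1 deletion strain. Both SPL2 signals (17.6 and 142) lay under the background level, which leaves no measurable difference between the strains. With signals raised to that level, PHO89 lay at -3.21 ± 0.48 SE against wild type in the ada1 and -2.62 ± 0.48 SE in the gcn5 deletion strain. The list did not stand apart (median -0.27 at percentile 5.7, or -0.04 with dim genes at the background level), except without the filter (-0.51, percentile 0.12). Ribosomal protein genes had a median of 0.51, which turned to -0.22 against the wild-type arrays of like signal range and to -0.03 after quantile normalization. Glycolysis and fermentation genes had 0.65, which turned to -0.23 within those pairs and was 0.03 after quantile normalization, no longer apart. Each deletion array shared its signal range with another wild-type array, and of the 284 calls 278 kept their sign and 196 stayed at 2-fold or more in that direction as a difference of the within-pair differences.

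**Figure D4:**
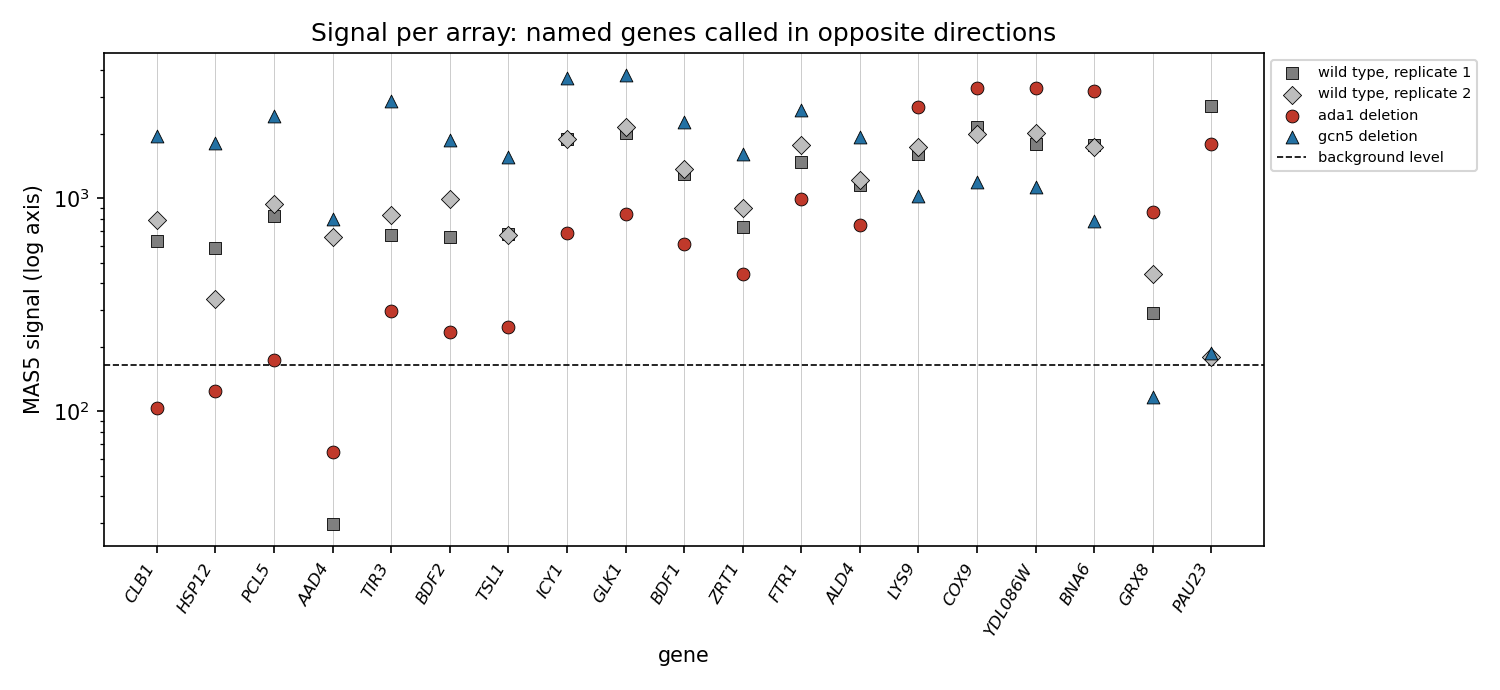
MAS5 signal on a log axis for the 19 named genes called in opposite directions against wild type in the deletion strains, with 1 point per array and the background level as a dashed line. CLB1 lies at 104 in the ada1 and 1966 in the gcn5 deletion strain, with 629 and 791 in wild type, and AAD4 and PAU23 follow the wild-type array of like signal range.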

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

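The tests of a-specific signals, of genes that differ between the wild-type arrays and of PHO84 between the deletion strains, and all comparisons within array pairs or with signals raised to the background level, were chosen only after the data were seen. A difference between the strains in their change from wild type set apart 21 genes called in opposite directions. That selection all but fixes the outcome of the test of ada1 against gcn5 deletion, which therefore adds no support. In 14 the ada1 deletion strain was the lower, among them CLB1, PCL5, HSP12, TSL1 and TIR3, which differed from each wild-type array by 2-fold or more in both strains, and the bromodomain genes BDF1 and BDF2. BDF2 gave 236 in the ada1 and 1879.8 in the gcn5 deletion strain against 658 and 993 in wild type. In 7 it was the higher, among them the nicotinic acid gene BNA6 (3202 and 788 against 1779 and 1740.1) and GRX8. Against the wild-type array of like signal range, 18 of the 21 kept both directions, which the selection against the wild-type mean also largely fixes. PAU23 turned in both strains (-0.58 in the ada1 and 0.07 in the gcn5 deletion strain), and for AAD4 and the unnamed probe set 1776828_at the ada1 and replicate 1 signals lay under the background level, which leaves no direction within that pair.

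The same difference set apart the general stress list, whose median in the ada1 deletion strain lay at -0.999 relative to the gcn5 deletion strain on the log2 scale, or at -0.64 with dim genes at the background level. It also set apart the daughter-specific and cell separation list at -1.47. Single genes of these lists were tested (12 of 31 and 12 of 15 lower), and the difference of the list medians itself was not tested.

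Alpha-specific genes were lower in both deletion strains, with medians of -3.17 and -3.49. Cultures of a/alpha cells would lower genes repressed in such cells as far. The median of RME1, NEJ1, GPA1, STE4, STE18, STE5 and FUS3 was only -0.67 in the ada1 and -0.20 in the gcn5 deletion strain (SD over genes 1.19 and 0.65). These genes did not move alike in the ada1 deletion strain, where RME1 (-2.28 ± 0.30 SE) and FUS3 (-1.75 ± 0.36 SE) lay well below the median. Cultures of a cells would bring abundant a-specific transcripts, but the signals of MFA1, MFA2, STE2, STE6, BAR1, AGA2 and ASG7 were at most 111 in the deletion strains, all under the background level of 166. The tables thus argue against cells of another mating type as the whole cause, and quantile normalization left medians of -3.09 and -3.62. The deletions themselves remain a candidate explanation, untested against a second culture of each strain.

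The PHO regulon was lower in both deletion strains. Chance measurement values of the shared wild-type arrays are argued against. Those arrays differed in the list median by only 0.0131, and each strain's median lay at -1.35 or lower against each of them. If both arrays came from 1 culture, their agreement says nothing about a chance PHO level of that culture. Only 3 of the 11 PHO genes called in both strains differed between the strains, PHO84, SPL2 and PHO89. Both SPL2 signals and the ada1 signal of PHO89 lay under the background level. A higher expression of PHO genes in the wild-type cultures, as from their phosphate state, would lower both strains alike. It thus cannot be told apart from the deletions for most genes. For PHO84 it is argued against as the whole cause, since a state of the wild-type cultures cancels between the deletion arrays and the ada1 deletion strain lay at least 19.9-fold lower than the gcn5 deletion strain, a log2 difference of -4.31 ± 0.36 SE with the ada1 signal raised to the background level (adjusted p = 0.000530, limma). The deletions remain open as an explanation, and the labels name no separate wild-type culture that would test it.

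The calls of ada1 against gcn5 deletion may follow the pairs of arrays with different signal ranges. Over the 284 calls the difference of the within-pair differences was 0.949 times the direct difference in the median. Of these calls 97.9 percent kept their sign (275 of 284 with signals raised to the background level). A call already had to exceed the spread of the trend, which was fitted to the same wild-type pair. For genes near that trend this outcome was therefore largely fixed beforehand. A gene's own wild-type difference carried no weight in its call. PAU23 and AAD4 were called at 3.26 and -3.63 despite differences of 3.91 and -4.47 between the wild-type arrays. The kept signs alone cannot tell whether the signal range caused most calls. After quantile normalization, which gives all arrays 1 distribution, 267 of the 284 were still called in the same direction. This argues against the signal range as the cause of those 267 calls, but not against another difference between the pairs. The medians of ribosomal protein genes (0.51 to -0.03) and of glycolysis and fermentation genes (0.65 to 0.03) went the other way. A separate split by pair remained in genes that differ 4-fold or more between the wild-type arrays, the named genes AAD4, DOG2, PAU17 (by a probe set that can detect similar genes), PAU23 and TPO2 and the unnamed probe sets 1773061_s_at and 1776828_at. All 7 kept that difference after quantile normalization, though only 6 have it with signals raised to the background level, so the signal range does not account for it, and in all 7 each deletion array lay closer to the wild-type array of its own range, in line with another difference shared within each pair. What that difference is was not tested, and it stays open for these genes beside the deletions.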

How the results depend on the processing

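No paired analysis was possible because each deletion strain has 1 array, so that a block leaves 0 residual degrees of freedom and comparisons within array pairs give values without a test. Comparisons within array pairs, signals raised to the background level, quantile normalization combined with the 2-fold rule, and all settings of the 2-fold count between the deletion strains were chosen after seeing the data. For ada1 deletion, gcn5 deletion, ada1 against gcn5 deletion and both strains, the main counts of calls were 383, 211, 284 and 84. They were 692, 390, 577 and 140 after quantile normalization (373, 197, 267 and 82 of the main calls kept), 740, 490, 557 and 188 after scaling to a common median, 245, 123, 187 and 48 with a single variance prior, and 256, 106, 135 and 42 with signals raised to the background level, which lowered the prior degrees of freedom from infinite to 8.44. The 2-fold rule left 210, 99 and 47 calls for ada1, gcn5 and both strains, and with quantile normalization it left 231 and 119 for ada1 and gcn5. Both deletion arrays as 1 group against wild type gave 21 calls, in a fit where differences between the deletion arrays add to the spread. The counts of calls otherwise lay within 1.5 times the main value with an offset of 32, no filter and the stricter filter. So did those against wild type in fits of only the groups compared. The genes called changed more than these totals. Of the main calls 299, 157, 231 and 62 were kept without a filter, and 284, 150, 199 and 58 with the stricter filter, which drops genes. Without a filter, which adds dim genes, the genes at 2-fold or more were 411 in ada1, 258 in gcn5 and 574 in ada1 against gcn5 deletion, against 217, 113 and 327. Leaving out each wild-type array gave 298 to 320 such genes in ada1 and 139 to 346 in gcn5, with 346 without replicate 2. Such fits had no residual degrees of freedom and tested no calls.

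Among lists that stood apart, the medians that reversed were those of hexose transport in ada1 (0.25) and nitrogen catabolite repressed genes in gcn5 (0.0118), both without the filter, and in ada1 against gcn5 deletion amino acid synthesis after median scaling (0.0014, at an unchanged percentile of 0.09 and still apart), ribosomal proteins after quantile normalization (-0.0334) and within pairs (-0.22), and glycolysis within pairs (-0.23). For the filter the added dim genes account for it, for median scaling its shift of all genes alike, and for the others the cause was not tested. PAU23 (-0.65) and AAD4 (0.84) reversed within pairs, but for AAD4 this rests on signals under the background level, and with those raised to it the value was -0.28. After quantile normalization 10 lists stood apart in gcn5, 5 of the main 6 among them. Of the other values of single genes 1301 counted as unchanged, 34 came past the threshold, 71 fell short of it and 88 moved. Values without a test were judged without the threshold. Those with a wild-type array left out were judged by the sign of called genes, and those within pairs by their distance from the main value. Of the list medians 644 counted as unchanged and 231 moved. The comparison of promoters with a TATA box was not run. A signal below background, as for PHO84, SPL2 and PHM6 in ada1, allows only a bound on the fall.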

Other observations

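The test of CHA1 was written before its result was seen, and the other values here are descriptive. Of 21 tested iron regulon genes 4 rose and 2 fell in the gcn5 deletion strain (5 and 5 adjusted over the list alone), with a median of -0.10 that stood apart only after quantile normalization (-0.21, percentile 0.42). Of 17 tested zinc, copper and thiamine genes 1 rose and 4 fell in the ada1 (3 and 5 adjusted over the list alone) and 3 rose and 2 fell in the gcn5 deletion strain (the same numbers adjusted over the list alone). The cell wall mannoprotein gene FIT3, of iron uptake, rose in both strains, from 3060.0 and 2264 to 6579 in the ada1 and 6818 in the gcn5 deletion strain. FET4, a low-affinity iron transporter gene, and ZRT2, a low-affinity zinc transporter gene, fell in both, FET4 from 1361 and 1316 to 603 and 442 and ZRT2 from 1489 and 1228 to 481 and 644. ZRT1, the high-affinity zinc transporter gene, and FTR1, the high-affinity iron permease gene, fell in the ada1 (443 and 997) and rose in the gcn5 deletion strain (1611 and 2607), from 735 and 903 and from 1489 and 1780.2. The zinc, copper and thiamine list had medians of 0.08 and 0.26 and did not stand apart.

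In the ada1 deletion strain RNR1, the large subunit of ribonucleotide reductase, fell from 2717 and 2367 to 854, and the cyclin genes CLN1, PCL2 and CLB6 also fell, so that 4 of 28 tested G1-S genes fell (5 adjusted over the list alone) and none was called in the gcn5 deletion strain. The G1-S median was 0.02 against wild-type replicate 1 and -0.42 against replicate 2, and with these opposite signs the list did not stand apart at its percentile of 0.05. It stood apart after quantile normalization (median -0.30, percentile 0.01) and after scaling to a common median (-0.21), which left the percentile as it was and turned the sign against replicate 1. In the ergosterol list of 24 genes ERG12 rose and ERG5, ERG28 and IDI1 fell in the ada1 deletion strain, while ERG9 fell in the gcn5 deletion strain (the same counts adjusted over the list alone). IMD2, of guanine nucleotide synthesis and read by a probe set that can detect similar genes, gave 115 in the gcn5 deletion strain against 889 and 439, the only call among 18 purine genes (3 rises and 1 fall adjusted over the list alone). The linker histone gene HHO1 fell from 1363 and 1583 to 703 in the ada1 deletion strain, the only call among 10 histone genes in either strain, as deposited. Of 16 tested seripauperin and anaerobic cell wall genes, TIR1 (279 against 2010.1 and 2389) and TIR3 fell and ANB1 and PAU23 rose in the ada1 deletion strain (the same adjusted over the list alone). TIR3, ANB1 and PAU17, by a probe set that can detect similar genes, rose and PAU23 fell in the gcn5 deletion strain (4 and 2 adjusted over the list alone). The medians were 0.24 and 0.09, the latter -0.08 after scaling to a common median and -0.01 after quantile normalization, and neither stood apart. Against the wild-type array of like signal range, PAU23 turned in both strains and PAU17 in the gcn5 deletion strain (1402 against 1561). In the gcn5 deletion strain the separate cell wall and flocculation list had 2 falls of 22, CWP1 and TIP1, also when adjusted over the list alone, and a median of -0.30 (percentile 1.22; apart after quantile normalization, -0.19, and without the filter, -0.28).

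A hypothesis was tested on SER3, which rose in the ada1 deletion strain. SER3 is known to be repressed by transcription of an upstream noncoding RNA that the activator Cha4 turns on, so a loss of Cha4-dependent transcription may raise it. It would then lower CHA1, the serine deaminase gene that Cha4 also activates. CHA1 fell from 2399.7 and 2177 to 776 in the ada1 deletion strain, a log2 difference of -1.56 (adjusted p = 1.49e-10, limma), as this explanation needs. In the gcn5 deletion strain SER3 (0.60, adjusted p = 0.291) and CHA1 (0.45, adjusted p = 0.302) were not called, and CHA4 itself gave 349 and 386 against 289 and 325. A single target gene on a single array carries this test, and the noncoding RNA was not measured here.

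The chromosome median furthest from the median over all genes lay at -0.11 relative to it on the log2 scale, for chromosome I in the gcn5 deletion strain. Of the genes next to HFI1 and GCN5, ATG41, the third gene on one side of HFI1, was called higher in the gcn5 deletion strain (0.91 on the log2 scale) and none was called in the ada1 deletion strain. Among unnamed probe sets, 1770054_at gave 41.1 in the ada1 deletion strain against 331 and 409.8 in wild type, and 1770455_at gave 2115 in the gcn5 deletion strain against 499.6 and 329.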
